A study of Homo sapiens with 6 samples.

How the data were processed

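RNA was measured by sequencing in 6 libraries of IOMM-Lee cells, 3 from normoxia and 3 from hypoxia at 0.2% oxygen for 48 h. Per the labels' protocols, cells grew in medium with 10% serum at 37 °C and 5% CO2, RNA with an integrity number of at least 9.0 was isolated on columns, and libraries were made with the NEBNext Ultra II RNA kit. How RNA was selected before library preparation, the strand setting of the counting and the annotation release are not given in the sources used here. Without a stated strand setting, reads of a gene and its antisense partner cannot be told apart. The labels call the libraries biological replicates, and groups and replicate numbers were taken from the sample titles.

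The deposited count table holds raw read counts per Ensembl gene. The submitters' processing notes name fastp 0.20.1, HISAT2 2.1.0, featureCounts 2.0.1, DESeq2 1.37.5 and the build GRCh38.p13. The table has 61860 lines. Of these, 1 names no gene, has values for the normoxia libraries alone and holds 0.00243% of all counts, and it was left out of library sizes and tests. Of the 61859 genes, 40297 had at least 1 count, 61756 matched a symbol and 58307 a gene type. Coordinates, gene types, GC content and exon length are from GENCODE release 29 on GRCh38.

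A second deposited table is named for FPKM and normalized counts. Its cells run together. Each line was therefore split where its values matched the raw counts times 1 factor per library, within a relative tolerance of 1e-06. The match of the 91917 values above 0 follows from this rule. Of 17907 lines, 0 failed to split in this way, so the values were taken as counts divided by size factors and not per kilobase. This table lists part of the genes, 17772 of them protein-coding. The alternatives planned for FPKM values were run on it under that reading.

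Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the group (minimum count 10, minimum total 15), which left 16411. TMM factors were 1.07 to 1.16 in normoxia and 0.866 to 0.927 in hypoxia. The quasi-likelihood F test with robust dispersions compared hypoxia with normoxia, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The SE of a log2 change is its size divided by the square root of F. The biological coefficient of variation was 15.3%. CPM values use TMM-scaled totals, and log2 CPM a prior count of 2. Within groups, counts of replicate pairs differed by more than sampling noise (chi-square per gene from 5.88 to 38.1), so no pair was treated as 1 library.

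41 gene lists with 933 entries were written before the data were examined. Lists with at least 5 tested genes, 38 in all, were compared with other genes by camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the lists. With an estimated correlation none was called, at adjusted p from 0.172 upward.

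The named genes followed a rule set before the data were examined. It took the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05, mean CPM of at least 10, groups that did not overlap and a symbol that is not an identifier, clone name or pseudogene. The code also left out symbols that begin with LINC or MIR and a digit. At first it dropped genes of RNA types too, which was corrected after the values were seen. The rule added up to 3 members per list in the main direction and 2 in the other with mean CPM of at least 1. It also added the 5 most abundant genes changed at least 2-fold, and 16 fixed genes. Not every gene the rule takes is printed.

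The scripts were tested on simulated counts for the hypoxia against normoxia comparison, with 200 genes changed among those with the real means and library sizes. Of 16411 simulated genes, 15954 passed the filter. In the edgeR test, 19.4% of the genes changed 1.5-fold, 65.7% of those changed 2-fold and 89.4% of those changed 4-fold were called, all with the right sign. False calls, 11 of 16211 unchanged genes, were 8.66% of the edgeR calls, and the share was 16.6% for DESeq2, 16.3% with a replicate block, 8.00% for limma-voom and 8.73% for limma on log2 values. Each of these shares lies above the nominal 5%. They come from 1 simulated data set with 200 genes changed, whereas 62.2% of the tested genes were called in the real comparison. The shares therefore do not carry over to the real calls. In a second simulation, camera called 5 of 5 shifted lists and 0 of 35 others, and with an estimated correlation 3 of 5. Its genes were drawn independently of each other, so it could not show false list calls that arise from correlated genes.

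Alternatives were DESeq2 1.42.0, limma-voom, other scalings (RLE, upper quartile, library totals), no filter and a stricter filter (CPM of at least 1 in 3 libraries), a replicate block, and limma on the deposited normalized values with pseudocounts of 1 and 0.1. Others left out the 10 most abundant genes, kept protein-coding genes, used an adjusted p of 0.01 or a test against a 1.2-fold change, or left out each library in turn. A correction for GC content and length (loess with a span of 0.5) and a scaling without ribosomal protein and mitochondrial genes were added after the data were seen.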

Results

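The series measured RNA in IOMM-Lee cells, an established line derived from a malignant (grade 3) meningioma, a tumour of the membranes around the brain. Libraries were made from 3 biological replicates grown in normoxia and 3 kept for 48 h in a hypoxia workstation at 0.2% oxygen. The normoxia libraries held 19554178, 14685317 and 16049763 counts and the hypoxia libraries 10980973, 10619864 and 18447885. A floor of 3 counts per library corresponded to between 0.133 and 0.316 CPM, counts scaled by the TMM-adjusted library total, and such floors cover counting error only. The comparison asked how prolonged low oxygen changed gene expression in these cells. Levels below are CPM as mean ± SD (n = 3 per group), and each change is hypoxia against normoxia with its standard error (SE).

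The libraries separated by oxygen first. The first principal component of log2 CPM held 80.9% of the variance and placed the normoxia libraries between -78.0 and -74.8 and the hypoxia libraries between 74.4 and 80.6. The second, with 7.83%, set hypoxia replicate 3 at -47.7 apart from the other hypoxia libraries at 27.2 and 20.1. Mitochondrial genes took 6.87% ± 0.435 of the counts in normoxia and 2.46% ± 0.521 in hypoxia (SD, n = 3). Cytosolic ribosomal protein genes took 8.82% ± 1.24 in normoxia and 11.8% ± 2.13 in hypoxia, and these ranges overlapped, from 8.03% to 10.3% and from 10.1% to 14.2%.

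**Figure D1:**
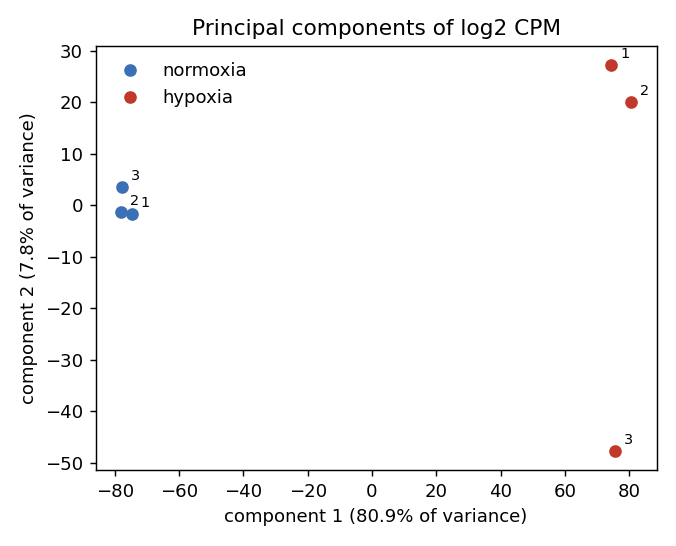
Principal components of log2 CPM, with component 1 (80.9% of the variance) on the x axis and component 2 (7.83%) on the y axis, in arbitrary units; each point is a library and the digit is its replicate number. The normoxia and hypoxia libraries lie at opposite ends of component 1, and hypoxia replicate 3 lies apart on component 2 at -47.7.

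Most of the tested genes differed between hypoxia and normoxia. NDRG1, a stress-response gene, rose 87.6-fold, from between 99.4 and 125 CPM in the normoxia libraries to 9798 ± 943 CPM, and the glycolytic enzyme GAPDH rose 4.66-fold to 10791 ± 950 CPM. The largest falls among genes with mean CPM of at least 10 included SEMA3E, which encodes a secreted semaphorin guidance cue, 23.8-fold lower, and CLSPN, a replication checkpoint adaptor, 13.3-fold lower. Of 16411 genes tested, 5117 rose and 5091 fell, which together is 62.2% (edgeR quasi-likelihood test, adjusted p under 0.05). Changes of at least 2-fold numbered 2670 up and 2900 down, and 288 genes rose and 282 fell at least 8-fold. The groups did not overlap for 67.9% of the tested genes, where chance gives 10% for any single gene. All genes share the same libraries, so the gap between these shares is not a test. Scaling by library totals alone shifted the median of all genes by -0.31 on the log2 scale and gave 3421 higher and 6905 lower, so that 33.1% of the changed genes were higher, against 50.1% with the TMM scaling used here.

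Known oxygen-responsive genes rose in every hypoxia library. CA9 (ENSG00000107159, GRCh38 chromosome 9, 35673856 to 35681159), a carbonic anhydrase at the cell surface, went from 70.7 ± 14.9 to 929 ± 32.0 CPM, a log2 change of 3.72 ± 0.15 (SE; edgeR adjusted p = 2.38e-08). The angiogenic factor VEGFA rose from 62.6 ± 0.851 to 685 ± 280 CPM, the glucose transporter SLC2A1 9.62-fold, the pyruvate dehydrogenase kinase PDK1 5.67-fold, the mitophagy receptor BNIP3 18.8-fold and ANKRD37 56.0-fold. EGLN3, an oxygen-sensing prolyl hydroxylase, had 30 counts over the 6 libraries and was not tested. Among regulators, EPAS1, which encodes HIF-2alpha, rose 12.9-fold from 18.4 ± 1.29 to 237 ± 103 CPM, while HIF1A rose 1.47-fold and its partner ARNT 1.71-fold. The HIF1A rise was lost with library totals alone (log2 change 0.25, edgeR adjusted p = 0.146). VHL, which targets HIF subunits for degradation, was at 31.5 ± 3.52 and 25.7 ± 3.25 CPM (edgeR adjusted p = 0.0841). It passed the threshold without hypoxia replicate 3, at a log2 change of -0.44, with library totals alone, at -0.60, with upper-quartile scaling, at -0.36, and with no filter on low counts, at -0.41. NF2 (ENSG00000186575, chromosome 22, 29603556 to 29698598), the tumour suppressor most often lost in meningioma, fell 3.00-fold from 238 ± 19.0 to 79.2 ± 16.9 CPM.

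**Figure D2:**
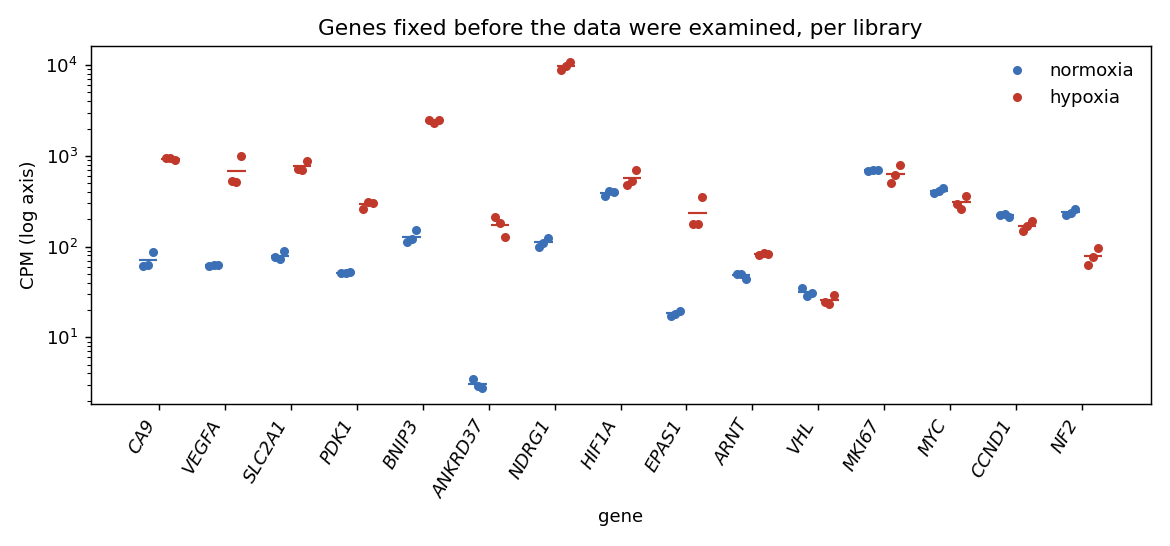
Level of 15 genes fixed before the data were examined, in CPM on a log axis; each point is a library (3 normoxia in blue, 3 hypoxia in red) and each line a group mean. NDRG1 lies at 112 CPM in normoxia and 9798 CPM in hypoxia, whereas the groups overlap for VHL and MKI67.

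The next rankings cover called genes with a gene symbol, mean CPM of at least 10 and groups that did not overlap. Symbols that begin with LINC or MIR and a digit were left out. The largest rises were in NGFR, RNF150, NDRG1, IGFBP3, HILPDA, PPFIA4, NOG, ADM, KRT17 and CRABP2, at log2 changes from 8.27 to 5.86. NGFR (ENSG00000064300, chromosome 17, 49495293 to 49515017), the low-affinity neurotrophin receptor, rose from 0.947 ± 0.233 to 296 ± 208 CPM, with 401, 431 and 55.6 CPM in the hypoxia libraries. Its call was lost with limma-voom (adjusted p = 0.0649). RNF150 rose from 0.111 ± 0.124 CPM, a mean under the floor, to 26.6, 27.6 and 8.13 CPM in the hypoxia libraries, and its log2 change of 7.47 ± 0.81 (SE) became 8.43 without normoxia replicate 2. IGFBP3, a secreted binder of insulin-like growth factors, rose 72.2-fold, with a log2 change of 6.17 that became 5.59 without hypoxia replicate 3. HILPDA, a lipid droplet protein, rose 69.7-fold, the BMP antagonist NOG 62.1-fold and the vasoactive peptide gene ADM 61.5-fold. Under the same limits the largest falls were in MT-TC, H2AC16, SEMA3E, RNASEH1, MT-TN, SH3TC2, CLSPN, H3C1, H2BC8 and PRMT6, at log2 changes from -4.93 to -3.66. MT-TC and MT-TN, neighbouring mitochondrial transfer RNA genes, went from 92.8 ± 29.3 to 3.13 ± 0.700 CPM and from 53.5 ± 17.5 to 3.90 ± 1.69 CPM. RNASEH1, an RNase that removes RNA from RNA-DNA hybrids, went from 27.2 ± 0.916 to 1.46 ± 0.487 CPM. H2BC8 changed by -3.67 on the log2 scale, or -4.30 without hypoxia replicate 1. Among abundant genes, the intermediate filament gene VIM rose 2.01-fold to 6149 ± 930 CPM.

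Of 22 glycolysis genes, 21 rose and 1 fell (camera adjusted p = 7.52e-11, but adjusted p = 0.237 with an estimated correlation). PFKFB4, which raises a potent activator of glycolysis, rose 39.5-fold, the glucose transporter SLC2A3 25.6-fold and the enolase ENO2 21.3-fold. The exception was the phosphofructokinase PFKM, 1.22-fold lower, whose edgeR adjusted p rose to 0.0512 without normoxia replicate 2 and 0.0665 without normoxia replicate 3. ALDOA, named after its values were seen, overlaps another annotated gene on the same strand, so that its 4.58 ± 0.233 CPM in normoxia is uncertain. In the oxygen sensing and HIF feedback list, 11 of 15 rose and 2 fell (camera adjusted p = 0.000667, adjusted p = 0.237 with an estimated correlation). The repressor gene BHLHE40 rose 15.2-fold and ARNT2 had a log2 change of -2.72.

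Of 12 collagen-modifying enzymes, 9 rose and 0 fell (camera adjusted p = 0.000667, adjusted p = 0.237 with an estimated correlation). Lysyl oxidase LOX rose by 4.32 on the log2 scale and the collagen prolyl hydroxylases P4HA2 and P4HA1 rose 13.3-fold and 12.5-fold. Of 15 angiogenic and secreted factors, 9 rose and 4 fell (camera adjusted p = 0.0257, adjusted p = 0.445 with an estimated correlation), and the growth factor FGF2 was among the falls at 2.93-fold lower. In the epithelial-mesenchymal transition list, 14 of 20 rose and 1 fell (camera adjusted p = 0.00128, adjusted p = 0.445 with an estimated correlation). The cytokine TGFB1 rose 5.07-fold and the fibronectin receptor subunit ITGA5 3.44-fold, while the transcription factor TWIST2 fell from 41.8 ± 6.18 to 20.8 ± 3.51 CPM. Of 19 JmjC and TET dioxygenases, enzymes that use oxygen to modify proteins or DNA, 14 rose and 1 fell (camera adjusted p = 1.63e-05, adjusted p = 0.409 with an estimated correlation). JMJD6 rose 14.8-fold and the histone demethylase KDM3A 7.77-fold, and KDM4A was 1.48-fold lower.

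Of 37 DNA replication genes, 34 fell and 2 rose (camera adjusted p = 2.41e-10, adjusted p = 0.172 with an estimated correlation). The helicase subunit MCM3 went from 69.5 ± 2.67 to 7.66 ± 1.21 CPM and the flap endonuclease FEN1 was 8.58-fold lower. The rises were in the licensing factors ORC1 and CDT1, at 1.68-fold and 1.36-fold, and both calls were lost with library totals alone (edgeR adjusted p = 0.0509 and 0.307). The CDT1 call was also lost with no filter on low counts (0.0533) and after GC content and length correction (0.943). Of 30 replication-dependent histone genes, 22 fell and 0 rose (camera adjusted p = 1.98e-06, adjusted p = 0.445 with an estimated correlation), and H3C1 was 13.2-fold lower. Near-identical histone copies can share reads, so single members are uncertain. Of 25 homologous recombination and Fanconi anaemia genes, 24 fell (camera adjusted p = 1.78e-07, adjusted p = 0.237 with an estimated correlation), among them BLM, 6.71-fold lower, and BRCA2, 4.27-fold lower. Of 7 mismatch repair genes, 6 fell and 1 rose (camera adjusted p = 0.0395, adjusted p = 0.337 with an estimated correlation). That call was lost without hypoxia replicate 1 (adjusted p = 0.0518), with library totals alone (0.0531) and after GC content and length correction (0.108).

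Of 34 mitosis genes, 24 fell and 0 rose (camera adjusted p = 0.000149, adjusted p = 0.445 with an estimated correlation), with CDK1 2.52-fold lower and HMMR 3.33-fold lower. The proliferation marker MKI67 was at 698 ± 9.59 CPM in normoxia and 637 ± 148 in hypoxia (edgeR adjusted p = 0.461). Its log2 change of -0.13 became -0.35 without hypoxia replicate 3 (edgeR adjusted p = 0.00835), -0.44 with library totals alone (adjusted p = 0.0271) and 0.0014 without hypoxia replicate 1 (adjusted p = 0.993). MYC was 1.35-fold lower (edgeR adjusted p = 0.011, or 0.0596 without hypoxia replicate 2) and the cyclin gene CCND1 1.30-fold lower. Of 22 p53 targets, 17 rose and 1 fell (camera adjusted p = 0.00089, adjusted p = 0.237 with an estimated correlation). The pro-apoptotic gene BBC3 rose 3.32-fold and the damage-recognition gene DDB2 3.03-fold, whereas XPC was 2.59-fold lower.

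Of 13 mitochondrially encoded protein genes, 11 fell (camera adjusted p = 0.000769, adjusted p = 0.445 with an estimated correlation). MT-CO3, a cytochrome oxidase subunit, went from 4522 ± 140 to 452 ± 165 CPM and MT-ATP6 from 6341 ± 518 to 1062 ± 374 CPM. Reads of these genes can also match nuclear copies. Of 18 tricarboxylic acid cycle genes, 12 fell and 3 rose (camera adjusted p = 0.0257, adjusted p = 0.467 with an estimated correlation), with OGDH 3.89-fold lower and IDH3G 1.98-fold higher. The cycle's call was lost after GC content and length correction (adjusted p = 0.0531). Of 29 ribosome biogenesis genes, 21 fell and 4 rose (camera adjusted p = 0.00037, adjusted p = 0.411 with an estimated correlation), including NOP56, 5.02-fold lower. Of 14 fatty acid synthesis genes, 10 fell and 4 rose (camera adjusted p = 0.0269, adjusted p = 0.445 with an estimated correlation). FASN was 3.21-fold lower and the desaturase gene SCD 1.53-fold higher, and this call was lost without hypoxia replicate 1 (adjusted p = 0.0518). Of 76 cytosolic ribosomal protein genes, 62 rose and 0 fell, with a median log2 change of 0.78 (camera adjusted p = 3.01e-07, adjusted p = 0.508 with an estimated correlation). With library totals alone the median was 0.47 and 69 of the 76 lay above 0. RPS19 rose 2.53-fold, with an edgeR adjusted p of 0.0562 without hypoxia replicate 3. RPS27 and RPL36 rose 2.58-fold and 2.44-fold. Both calls were lost with library totals alone (edgeR adjusted p = 0.0615 and 0.0782) and with a replicate block (0.0879 and 0.101). They were also lost with no filter and without normoxia replicate 1 or 2 or hypoxia replicate 1 or 3. The RPL36 call was lost after GC content and length correction too (0.0714).

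Of 14 NF-kB and cytokine genes, 9 rose and 2 fell (camera adjusted p = 0.0332, adjusted p = 0.411 with an estimated correlation). The feedback inhibitor TNFAIP3 rose 7.93-fold and the cytokine IL11 7.06-fold, while IL1B was 2.35-fold lower. The list's call was lost on the deposited normalized values (adjusted p = 0.0563). Of 11 immediate early genes, 7 rose and 2 fell (camera adjusted p = 0.0257, adjusted p = 0.337 with an estimated correlation). The list's call was lost after GC content and length correction (adjusted p = 0.085). IER3 was 6.89-fold, DUSP1 4.88-fold and EGR1 4.26-fold higher. DUSP1 was at 282, 244 and 923 CPM in the hypoxia libraries, and its log2 change of 2.29 became 1.38 without hypoxia replicate 3. Its call was lost without each normoxia library in turn and with no filter on low counts. Of 23 interferon-stimulated genes, 15 fell and 2 rose (camera adjusted p = 0.00166, adjusted p = 0.237 with an estimated correlation). OAS2 was 6.71-fold and IFIH1 5.36-fold lower, both sensors of viral RNA or its products, and the rises were in the transcription factors IRF7 and IRF9, at 3.24-fold and 2.70-fold.

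**Figure D3:**
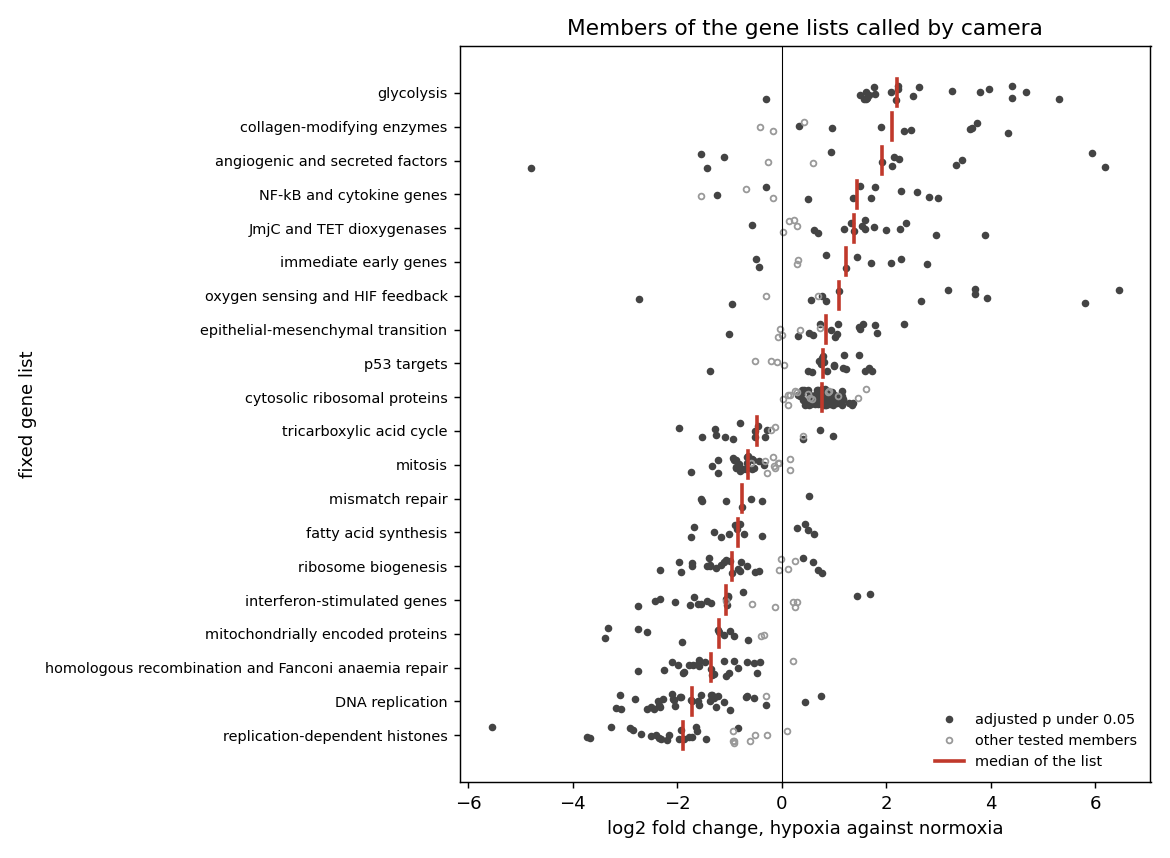
Log2 fold change (x axis, hypoxia against normoxia) of the tested members of the 20 gene lists called by camera (y axis); filled points have an edgeR adjusted p under 0.05, open points do not, and red bars are medians. List medians run from -1.89 for replication-dependent histones to 2.21 for glycolysis.

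The other 18 tested lists were not called, at camera adjusted p from 0.0525 to 0.95. Autophagy and mitophagy had 13 of 22 genes up and 7 down, with BNIP3L 8.36-fold higher. This list was called higher without hypoxia replicate 2 (camera adjusted p = 0.0407), with library totals alone (0.0207), on the deposited normalized values (0.0382) and after GC content and length correction (0.038). In the main fit with an estimated correlation its camera adjusted p was 0.445. ATF4 targets had 12 of 20 up and 5 down, with DDIT3 at a log2 change of 2.38 and SLC7A11 5.00-fold lower, and ER chaperones and ERAD had 13 of 23 up and 9 down. Matrix proteins and proteases had 9 of 20 up and 3 down, with COL5A1 23.1-fold higher and the urokinase gene PLAU 7.10-fold lower. Counts up and down were 6 and 5 of 16 for glycogen metabolism, 5 and 3 of 9 for pH regulation, 4 and 4 of 12 for lipid droplet and fatty acid uptake, and 6 and 3 of 13 for iron and heme. They were 13 and 17 of 75 for the nuclear-encoded respiratory chain, 10 and 22 of 56 for the mitochondrial ribosome, 4 and 6 of 24 for cholesterol synthesis, and 4 and 4 of 14 for cytosolic heat shock proteins. They were 5 and 5 of 15 for antigen presentation, 2 and 4 of 9 for immune checkpoint and adenosine genes, 5 and 9 of 20 for YAP and TEAD targets, and 3 and 2 of 11 for meningioma driver genes. Meningioma and arachnoid markers had 4 of 8 up and 1 down, with CRABP2 58.1-fold and the desmosome gene DSP 3.01-fold higher, and were called higher with the stricter filter on low counts (camera adjusted p = 0.0346). With the main filter and an estimated correlation the camera adjusted p of these markers was 0.409. Neural and glial markers had 1 of 8 up and 4 down. For leukocyte, endothelial and keratinocyte markers only 2, 4 and 2 genes were measured well enough to test, of which 1 rose, 2 fell and 1 fell. The median and the camera direction differed in sign for the respiratory chain, lipid droplet and iron lists, and the mean differed for the respiratory chain and heat shock proteins.

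Adjusted over the list alone, the counts of members that rose or fell were the same except in 7 lists. These gave 66 ribosomal protein genes up, 15 JmjC and TET dioxygenases up, 14 ATF4 targets up, 8 immediate early genes up, 2 neural and glial markers up, 3 NF-kB and cytokine genes down, and 7 respiratory chain genes up with 14 down.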

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

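The GC content and length correction and the scaling without ribosomal protein and mitochondrial genes were chosen after seeing the data. The count of changed genes, 10208, ranged from 8024 to 11339 over the settings that kept all libraries and from 9065 to 10913 when a library was left out. Changes of at least 2-fold, 5570, numbered 3814 to 6966 over the former and 5461 to 5879 over the latter. Rises of at least 2-fold numbered 1769 among protein-coding genes only, where fewer genes were tested. DESeq2 kept 96.9% of the calls, and library totals alone 83.4%, with 72 shared calls of other sign. The GC content and length correction kept 87.9%, with 104 of other sign. Before it, the median log2 change of protein-coding genes was -0.31 in the lowest decile of GC content and 0.45 in the highest. Leaving out 1 library kept 85.0% to 94.2% of the calls tested in both, with 20 of other sign without hypoxia replicate 3. The median of all genes shifted by -0.31 with library totals alone and by -0.12 with no filter on low counts.

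With the replicate block, 9768 genes were called, 4862 higher and 4906 lower. The numbers were not read as pairs because the labels do not say that they mark a shared day or batch. Same-numbered libraries deviated from their group means with correlations of -0.11, 0.09 and -0.04. Normoxia replicate 3 and hypoxia replicate 1 reached 0.18, and so few libraries cannot exclude pairing. With the block, 20 lists were called, 20 of them shared with the fit without it.

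Of 20 lists called, 0 were called with an estimated correlation, 0 higher and 0 lower; fry, which does not compare a list with other genes, called 30, of which 18 higher. Leaving out a library gave 18 to 21 called lists, 10 to 11 higher and 8 to 10 lower. The 225 genes named by the rule or after their values were seen had 4678 values under other settings. Of these, 4597 kept direction and side of the threshold, 63 lost the call, 16 gained one and 2 reversed. The rule picked most of these genes because they passed the threshold, as 219 of the 225 did. Their stability therefore does not stand for that of all calls. Neither reversed gene was called: MKI67 went from -0.13 to 0.0014 without hypoxia replicate 1 and -0.35 without hypoxia replicate 3, and SEMA3C from -0.27 to 0.044 after GC content and length correction; the cause was not tested. Genes with few counts in a group, such as RNF150 at 0.111 CPM in normoxia, have folds limited by depth.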

Other observations

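Tests chosen only after the result was seen were those on GC content and length, scaling, ribosomal protein pseudogenes, DNA replication genes and untailed RNAs with mean CPM of at least 10. The genes in this paragraph were also chosen after their values were seen. Of the pyruvate dehydrogenase kinases, PDK1 rose 5.67-fold and PDK3 3.25-fold, PDK4 was 4.52-fold lower, and PDK2 had a log2 change of -0.26 (edgeR adjusted p = 0.142). PDK2 passed the threshold with library totals alone, at -0.58, and after GC content and length correction, at -0.53. PFKFB3, like PFKFB4, rose, at 4.26-fold, while PFKFB2 had a log2 change of -1.92. Of the semaphorin genes looked at, SEMA3E and SEMA3A fell, SEMA3B rose 1.86-fold, and SEMA3C did not pass the threshold at a log2 change of -0.27 (edgeR adjusted p = 0.306). SEMA3C fell by 0.64 without hypoxia replicate 3, 0.58 with library totals alone and 0.38 with no filter on low counts, each past the threshold, and was at 0.04 after GC content and length correction. Of the semaphorin receptors, PLXND1 was 5.95-fold lower and NRP1 changed by -0.38 (edgeR adjusted p = 0.0756), or by -0.67 without hypoxia replicate 3, -0.70 with library totals alone, -0.50 with no filter and -0.46 with upper-quartile scaling, each past the threshold. The lactate dehydrogenase gene LDHB had a log2 change of -0.46 (edgeR adjusted p = 0.0191), a call lost after GC content and length correction (0.117), without normoxia replicate 3 (0.0719) and without hypoxia replicate 2 (0.0576). The cyclin-dependent kinase inhibitor genes CDKN1A, CDKN1B and CDKN1C rose 2.77-fold, 3.74-fold and 5.53-fold, PCNA was 5.16-fold lower and TOP2A 1.74-fold lower. The long non-coding RNAs MALAT1 and MEG3 rose 3.96-fold and 3.70-fold, whereas of 746 lincRNA genes tested 142 rose and 277 fell.

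Cytosolic ribosomal protein genes were higher in hypoxia, with a median log2 change of 0.78 (median absolute deviation 0.312). Removing each library's trend on GC content and length left it at 0.79, with 63 of 76 genes called, although the rank correlation of fold change with GC content over all genes went from 0.192 to -0.0046. Length was that of all annotated exons of a gene together, not of its mature transcript. An effect of transcript length therefore stays open. With library totals alone, the median was 0.47 (median absolute deviation 0.312) and 69 of the 76 lay above 0, which argues against the TMM factors as the whole source. Processed pseudogenes of these genes were also higher, with a median of 0.79 over 142. A move of reads from pseudogenes to parents would lower the pseudogenes, so this argues against it as the whole source. Pseudogenes can also share reads with their parents and rise with them, so a partial move stays open. A response to hypoxia remains a hypothesis, and differences in RNA handling between the groups stay open because the labels give no batch.

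Replication-dependent histone genes had a median log2 change of -1.89 (median absolute deviation 1.30), and most of their messages lack a poly(A) tail. Other such RNAs (65 small nuclear, nucleolar and related genes) had a median of 0.96 (median absolute deviation 1.15), with 20 called higher and 7 lower. The 9 with mean CPM of at least 10 lay above 0, with a median of 1.30 (median absolute deviation 0.583). Of these 9, 3 were called higher and 0 lower. These untailed RNAs thus showed no fall as a set, but whether their yield follows that of histone messages was not tested. A lower yield of histone messages in hypoxia therefore stays open. After GC content and length correction the histone median was -2.13. DNA replication genes, whose messages are tailed, were lower for 34 of 37, which is consistent with the hypothesis of fewer cells replicating their DNA, while MKI67 did not pass the threshold.

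Of 697 processed pseudogenes tested 256 rose and 51 fell, and of 169 sense-intronic transcripts 80 rose and 16 fell. Across 517 pseudogenes with a tested parent, the fold changes of both had a Spearman rho of 0.335, and across 155 sense-intronic transcripts and hosts 0.439. Pearson correlations were 0.289 and 0.626. The hosts had a median log2 change of 0.31, with 106 of 155 above 0, and transcript minus host a median of 0.77 (median absolute deviation 1.27). Both Spearman values are across genes, which are not independent replicates, and lie between the limits of 0.2 and 0.5 set in advance for rho. Shared reads and unspliced host RNA therefore cannot be told apart from transcription of these loci. Genomic DNA in the hypoxia libraries stays open too. The highest share of counts in untested genes was 0.336% in hypoxia against 0.381% in normoxia, a gap smaller than the SD of 0.0667 between normoxia libraries.

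The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For genes changed, 1 split, the real one, gave as many as 10208, and the highest other gave 0 (edgeR; 245 genes at most had an unadjusted p under 0.05). For changes of at least 2-fold the values were 1 split, 5570 genes and 0. For lists called by camera they were 1 split, 20 lists and 14, so that mixed groups also gave many list calls with the preset correlation. Each split other than the real one put both oxygen levels in both groups. The oxygen difference then added to the spread within groups, so few gene calls could arise. Part of it also remained between the groups, so these splits do not measure false calls for genes or lists.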
